A study of Mus musculus with 2 samples.

How the data were processed

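The measurements were peak lists of H3K4me1 ChIP-seq in the stomach of mixed-sex pools of B6NCrl mouse embryos at day 16.5, from 1 group with 2 biological replicates. Per the labels, replicate 1 combined 2 technical replicates, sequenced on 2 instrument models, and replicate 2 had 1; the stated size range was 300 to 500 bp in both. The authors made all 4 lists before deposit. Per the text files deposited with them, each replicate's list came from its filtered alignments together with control alignments, the pooled list from the alignments of both replicates with controls, and the replicated list from the pooled list and the separate lists. The assembly was mm10, per the labels. The aligner, the peak caller and its settings are not given in the sources used here, and control libraries were not analysed here. Peaks were thus called per replicate and again on the pool, so the separate lists can be compared as replicates, while the pooled and replicated lists depend on both.

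Each peak in the deposited lists has an enrichment value from the authors' peak caller. It was read here as a ratio from the narrowPeak format and from its values, since no source used here defines it. Each peak also has −log10 of a p-value and of a q-value, also deposited by the authors. The lowest −log10 p in any list was just over 2, so weak peaks were kept. Peaks with −log10 q of at least 2 made up 70.1% of replicate 1, 64.7% of replicate 2, 76.2% of the pooled and 93.3% of the replicated list. Enrichment values are the authors' own and were used only to rank, filter and describe peaks and to correlate shared regions. The median enrichment was 3.18 in replicate 1, 3.32 in replicate 2, 3.05 in the pool and 3.46 in the replicated list, and the median width 289, 276, 302 and 443 bp. The lists covered 63.5, 50.7, 71.7 and 52.6 Mb. Read numbers per library are unknown here, so differences in the number of peaks between the replicates cannot be set against depth. A peak list also holds nothing below its threshold: a gene without a peak is one without a call, which is not evidence that the mark is absent.

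Peaks on the 19 autosomes, X and Y were kept, which left out 2 peaks of replicate 1 and 1 peak of each of the other lists on unplaced scaffolds. Peaks of a list that overlap or touch would have been joined, and none did. Chromosome lengths, assembly gaps of at least 1000 bp and base composition came from the GRCm38 sequence and genes from GENCODE release M21 on the same assembly, and every peak end lay within its chromosome. Coordinates are 1-based. Regions were called shared when at least 50% of their length was covered by the other list. The background for positions was 100 shuffles within chromosomes outside assembly gaps, with a fixed seed. A region was assigned by its midpoint to a promoter (within 1 kb of any annotated TSS), else an exon, else an intron, else intergenic sequence. The TSS profile took the outermost start of each protein-coding gene in 100 bp steps to 5 kb on each side. Promoters were CpG-rich with at least 55% GC and an observed over expected CpG ratio of at least 0.6 within 500 bp of the TSS, CpG-poor under 0.4, and otherwise intermediate.

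For each of 21911 protein-coding genes the percent of the window within 50 kb of the TSS covered by replicated peaks was computed. Windows and distances to protein-coding starts used the outermost start of each gene. In long genes much of the gene, with any later start, thus lies outside the window. A window can also hold starts of other genes, so its coverage cannot be assigned to the named gene alone. Gene lists were fixed before the data were examined. Their 1962 members all matched an annotated gene by current or older symbol. Each list's median was placed among 10000 random lists of the same size matched on the number of protein-coding TSSs in the window in 5 bins, and called high at or above the 98th percentile or low at or below the 2nd. These percentiles describe these libraries and are not p-values across samples. With 1 group of 2 replicates no test between groups was possible, and errors are the SD of the replicate lists, except for a 95% Wilson interval on the shares of regions found in the other replicate and bootstrap intervals over windows of the X chromosome. The Wilson interval covers the counting of regions only, takes neighbouring regions as independent and says nothing of the spread between libraries. Genes named were, by a rule also fixed beforehand, the 3 highest and the lowest of each list, the 10 highest genes at least 200 kb apart, the 10 domains with the most covered bases, the 5 widest and 5 strongest replicated peaks, and the widest regions found in 1 replicate alone; where room was short the first of each were taken. H19, Thbs3 and Pxn, as neighbours of such genes, were named after the values were seen. So were Opn1mw, Flna and Pgk1, and the further genes under other observations.

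The alternatives tried were a stricter q, the 50000 strongest peaks of each list, other overlaps, equal numbers of peaks, the mean enrichment of a region, each replicate alone, the pooled list, a promoter of 2 kb, a circular shift as background, the summit for the midpoint, all transcripts, windows of 20 and 100 kb, the number of regions, matching on gene length or GC content, and gaps of 2 and 12 kb for domains. Limiting the gene lists and the TSS profile to autosomes was added after the low number of X-linked peaks was seen. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures Matplotlib 3.10.9. The procedures were tested on simulated data. With 40.1% of 162493 shuffled regions planted in a second set, 41.2% were found shared, the surplus being overlaps of randomly placed regions. A planted rank correlation of 0.575 was returned as 0.554 over 65097 regions, with no calling threshold put on the second set. On shuffled peaks none of 20 random gene lists was called, and 19 of 20 lists with 3 added regions per gene were called high. Lists of clustered genes were not simulated. The promoter share of shuffled regions over that of another shuffle was 0.962, where 1 was the target. Covered lengths were right in all of 500 windows counted base by base.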

Results

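H3K4me1, the monomethylated form of lysine 4 of histone H3, was mapped by chromatin immunoprecipitation and sequencing in the whole stomach of mouse embryos of strain B6NCrl at embryonic day 16.5. H3K4me1 is commonly found on enhancers and on the flanks of active promoters. At this age the mouse stomach holds an epithelium that is still differentiating, a squamous forestomach, and a wall of mesenchyme, smooth muscle, vessels and enteric nerves. The series held 1 group of 2 biological replicates, each a pool of stomachs of both sexes. Replicate 2 was made from 41 embryos, and the number in replicate 1 was not given. The data were 4 deposited peak lists: 162493 peaks in replicate 1, 140549 in replicate 2, 169709 in the pool of both, and 92103 in a list of replicated peaks. Read depth was not analysed here and is unknown, so no value below carries a counting error from reads. With 1 group, the questions were where the mark lay, around which genes, and how far the replicates shared it. Coverage around genes is given as the percent of the 50 kb on each side of a gene's transcription start site (TSS) that lay in replicated peaks, with the mean ± SD of the separate replicate lists beside it where a gene is described in full.

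The gene with the highest H3K4me1 coverage in the genome was Ncor2, which encodes a nuclear receptor corepressor (mm10 chromosome 5, 125017153 to 125179219). It had 47.9% of its window in replicated peaks and 44.8% ± 4.30 (SD, n = 2) in the replicates. Ski, a repressor of TGF-beta signalling, followed with 43.8% (38.9% ± 6.74 in the replicates), and Rara, a retinoic acid receptor, with 43.3% (41.5% ± 3.48). The partner receptor Rxra had 38.1%, the transcriptional coregulator Zmiz1 38.3%, the methylcytosine dioxygenase Tet3 37.9% and the nonmuscle myosin heavy chain Myh9 37.3%. The anaphase-promoting complex activator Fzr1 had 38.0% and Ifrd2 36.4%. Mrpl23, a mitochondrial ribosomal protein gene with 39.0%, has the start of the imprinted noncoding RNA gene H19 45.5 kb away in its window. Across all 21911 protein-coding genes the median was 2.30%, the 99th percentile was 22.3%, and 4949 genes had no replicated peak in the window.

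Several of these loci led again when replicated peaks with gaps of up to 5 kb were joined into domains. The domain with the most covered bases lay inside Gse1 on chromosome 8 (120484071 to 120565922), with 52.7 kb covered by 45 peaks. A domain over the start and the 5′ part of Zmiz1 (chromosome 14, 25446972 to 25534771) also had 52.7 kb covered, and a domain at Ncor2 (chromosome 5, 125119914 to 125196312) had 49.8 kb. The others of the first 10 lay at Lrig1, a negative regulator of growth factor receptors, at Ski, inside Ssbp3, at the adaptor gene Shb, at the kinase gene Map4k4, at Rara and at Tet3, with 36.5 to 42.8 kb covered. In the single lists, 42.3 kb of the Zmiz1 domain was covered in replicate 2 and 51.2 kb in replicate 1. Of these 10 domains, 7 overlapped the first 10 of replicate 2 alone and 6 those of replicate 1 alone. The rank order moved with the gap allowed, since 4 of the 10 overlapped the first 10 at 12 kb and 6 at 2 kb.

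The widest and the strongest single peaks lay mostly in introns. The widest replicated peak spanned 7622 bp in an intron of Rara (chromosome 11, 98938739 to 98946360), and the next lay over a promoter of the Wnt coactivator gene Bcl9l (7139 bp) and in introns of Nfix, Ski and Akt1 (6837 to 6919 bp). The strongest peak lay in an intron of Vps13d (chromosome 4, 144997101 to 145000071). Of the outermost starts of protein-coding genes, the nearest was that of the retinol-metabolism gene Dhrs3, 106 kb away. The enrichment value of this peak, the authors' own value per peak, read here as a ratio, was 10.2. The peak overlapped peaks of 8.995 in replicate 1 and 8.44 in replicate 2. The next strongest lay in introns of the phosphatase gene Ptp4a3 (10.2), Erf (9.44), Slu7 (9.12) and Lasp1 (9.07). The replicates differed more at some of these, with overlapping peaks in replicates 1 and 2 of 10.9 and 6.37 at Ptp4a3, 8.38 and 8.22 at Erf, 8.62 and 6.12 at Slu7, and 9.61 and 5.92 at Lasp1.

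Of 29 gene lists fixed before the data were examined, 10 had a median coverage at or above the 98th percentile of 10000 random lists matched on gene density, and 2 lay at or below the 2nd. By chance 0.58 lists would be taken on each side if members were as independent as randomly drawn genes. Neighbouring members share windows, as Hoxa5 and Hoxa6 do, so that number is only a guide. By percentile, the Wnt, BMP and TGF-beta, and FGF and Notch lists stood highest, each at the 100th. The 24 Wnt pathway genes had a median of 7.05% against 1.23% in random lists, with Ror2, a Wnt5a receptor, at 21.1%, Tcf7l2, a transcription factor of the pathway, at 18.6% and the receptor Fzd2 at 13.9%. The lowest member was the secreted agonist Rspo3 at 0.927%. The 22 BMP and TGF-beta genes had a median of 6.52% against 1.49%, led by the signal transducer Smad3 at 35.7% (33.7% ± 5.51 in the replicates) and the inhibitors Smad7 at 31.7% and Smad6 at 22.9%, while the antagonist Grem2 had 0.580%. The 22 FGF and Notch genes had a median of 6.95% against 1.31%. The receptors Notch1 (34.1%) and Notch2 (31.5%) and the Notch target Hes1 (18.0%) led that list, and no replicated peak lay in the window of the growth factor Fgf10. All 3 lists lay above the 98th percentile in each replicate alone and under each of the 11 alternatives tried. The 16 hedgehog genes had a median of 5.28% against 1.76% (99.4th percentile), led by the receptor Ptch1 at 19.1% (19.8% ± 1.05), the co-receptor Boc at 13.3% and the dispatched-family gene Disp2 at 11.3%, with the inhibitor Hhip at 0.488%. In replicate 1 alone the hedgehog list lay at the 97.8th percentile, and among lists matched on the GC content of the window at the 87.3rd.

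**Figure D1:**
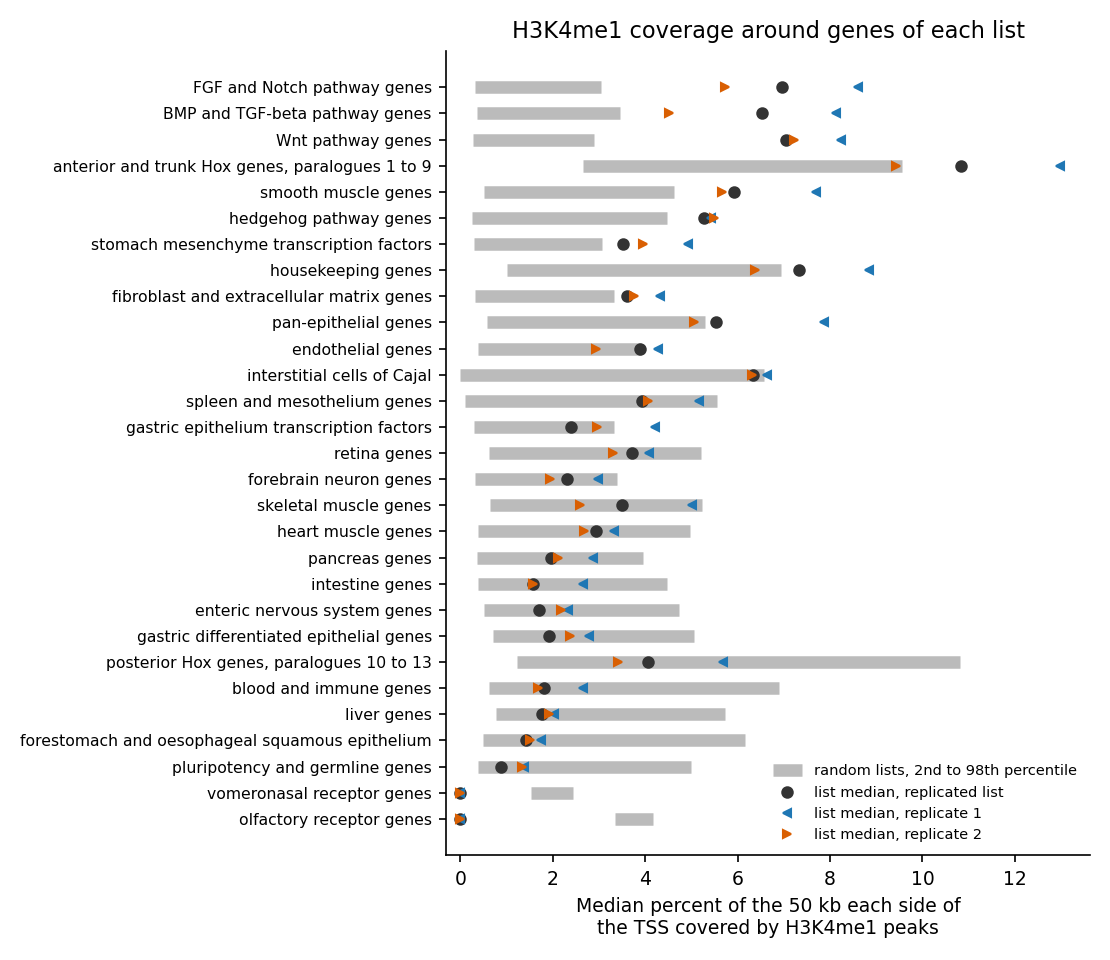
Median percent of the 50 kb on each side of the TSS covered by H3K4me1 peaks (x axis) for each of the 29 gene lists (y axis, ordered by percentile). Dark points are the replicated list, triangles the separate replicates, and grey bars the 2nd to 98th percentile of 10000 random lists for the replicated list; the FGF and Notch, BMP and TGF-beta and Wnt lists lie farthest right of their bars, and the receptor families at 0.

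The smooth muscle, mesenchyme and matrix lists were also high. The 21 smooth muscle genes had a median of 5.93% against 1.96% in random lists (99.8th percentile), with the tropomyosin genes Tpm1 and Tpm2 at 13.7% and 13.6% and the intermediate filament gene Des at 13.7%. The lowest was Mylk, the myosin light chain kinase, at 0.871%. Its window was set on the outermost start, and most of the gene (chromosome 16, 34745210 to 35002420) lay outside it. Any later start of Mylk was thus not examined. The 24 transcription factors of stomach mesenchyme had a median of 3.52% against 1.31% (99.2nd percentile). Pbx1, a homeobox cofactor, had 19.2% (17.3% ± 1.27), and the neighbouring forkhead genes Foxf1 and Foxl1, whose starts lie 43.6 kb apart on chromosome 8, had 10.2% and 9.24%. Twist1 had the least, 0.919%. The 20 fibroblast and extracellular matrix genes had a median of 3.60% against 1.43% (98.7th percentile), led by the collagen gene Col5a1 at 16.4%, Sparc at 14.2% and the PDGF receptor gene Pdgfrb at 12.2%, with Fap at 0.294%. Matching on GC content ended these 3 calls, leaving smooth muscle at the 96.3rd percentile, mesenchyme factors at the 87.3rd and matrix genes at the 89.7th. Matching on gene length left the mesenchyme factors at the 87.9th and matrix genes at the 89.2nd, and the 50000 strongest peaks left them at the 96.9th and 97.5th. Matrix genes also missed the bound with a 100 kb window (97.5th).

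Among epithelial lists, the general list was high and the stomach-specific lists were not, though the difference between them was not tested. The 18 pan-epithelial genes had a median of 5.53% against 2.41% (98.6th percentile), with the small GTPase Rab25 at 20.1% (19.5% ± 1.27), the keratin gene Krt8 at 16.6%, the claudin gene Cldn7 at 16.4% and Tacstd2 lowest at 0.420%. The windows of Rab25 and Cldn7 held 6 and 9 protein-coding TSSs, so their coverage cannot be assigned to these genes alone. Among lists matched on GC content the percentile of the pan-epithelial list was 51.5. The list lay just under the bound with matching on gene length (97.95) and with the 50000 strongest peaks (97.8). The 20 transcription factors of gastric epithelium had a median of 2.39% (89.2nd percentile), but 4.20% and the 97.8th, just under the bound, in replicate 1 alone, and 2.96% and the 95.6th in replicate 2 alone. Matching on gene length left them at the 54.0th and on GC content at 7.58. In that list were Grhl3 at 10.4%, Foxa3 at 9.67%, Spdef at 7.11% and Klf5 at 0.214%. Genes of the differentiated gastric epithelium, 21 in all, had a median of 1.93% (30.7th percentile, with 1.09 under GC matching, 62.3 in the pooled list and 65.2 with a 100 kb window). In that list the mucin gene Muc1 had 17.6%, with its TSS 13.9 kb from that of Thbs3. The pepsinogen gene Pgc had 8.85% and the ghrelin gene Ghrl 5.07%. No replicated peak lay near 5 members, among them the gastric lipase gene Lipf. The 17 genes of squamous epithelium had a median of 1.42% (14.2nd percentile, and 52.6 with a 100 kb window), with Lgals7 at 11.4%, Pitx1 at 9.87% and Itgb4 at 7.87%. No replicated peak lay within 50 kb of the outermost start of Trp63, the regulator of squamous basal cells. Most of that gene (chromosome 16, 25683763 to 25892102) lay outside the window, so any later start was not examined.

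Other cell types of the stomach wall fell near or below the upper bound. The 6 genes of interstitial cells of Cajal, the pacemaker cells of gut muscle, had a median of 6.33% (97.7th percentile, but 98.2 in replicate 2 alone and with the number of peaks as the measure, and 98.5 with the 50000 strongest peaks, against 95.9 in replicate 1 alone and 93.3 with windows of 20 and 100 kb), with the chloride channel gene Ano1 at 12.7%, Kitl at 10.2%, Entpd2 at 6.97% and Gja1 at 0.739%. The 20 endothelial genes had 3.89% (97.9th percentile, and 98.6 with −log10 q of at least 2, but 95.2 in replicate 1 alone, 89.0 in replicate 2 alone and 86.3 with a 100 kb window), led by Eng at 19.9%, Esam at 9.29% and Lyve1 at 8.41%, with Emcn at 0.349%. The 20 genes of the enteric nervous system had 1.70% (33.5th percentile, and 62.2 with a 20 kb window and 51.6 in the pooled list). There Hoxb5 had 14.3%, Tlx2 10.9% and the GDNF receptor gene Gfra1 6.13%, and 4 members, among them the X-linked Plp1, had no replicated peak. The 20 blood and immune genes had 1.82% (17.8th percentile), with Cd68 at 13.6%, Epor at 10.1% and Klf1 at 7.60%. Of these 20, 5 had no replicated peak, among them the X-linked Gata1. The 10 spleen and mesothelium genes had 3.92% (90.3rd percentile), with Pbx1, which is also in the mesenchyme list, followed by Upk3b at 9.95% and Msln at 9.15%, and Gpm6a at 0. With GC matching the Cajal cell, endothelial, enteric, blood and spleen lists lay at percentiles of 94.7, 80.5, 2.125, 8.225 and 49.0.

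Lists of other organs lay between the bounds. The percentiles were 64.4 for 18 pancreas genes, 37.3 for 16 intestine genes, 17.7 for 20 liver genes, 76.0 for 16 heart muscle genes, 82.0 for 18 skeletal muscle genes, 85.3 for 20 forebrain neuron genes, 86.3 for 16 retina genes and 8.74 for 16 pluripotency and germline genes. Single members were nonetheless well covered. The pancreatic factor gene Rbpjl had 14.4%, the apolipoprotein gene Apoa2 11.7%, the cardiac troponin gene Tnnt2 11.3% and Tdrd1 6.27%. The intestinal factor gene Cdx1 had 11.5% and neighbours Pdgfrb on chromosome 18. Slc17a7 had 13.5% and neighbours Rpl13a of the housekeeping list on chromosome 7, so their windows overlap. In the skeletal muscle list the troponin gene Tnnt3 had 32.4%, with its TSS 33.9 kb from that of Mrpl23, and in the retina list Gnat1 had 31.3%, with its TSS 92.1 kb from that of Ifrd2. With GC matching the heart, skeletal muscle and germline lists fell to percentiles of 0.6, 2.63 and 0.51, and the other 5 lay between 5.76 and 60.8. The heart list also moved with the window, to 27.8 with 20 kb and to 97.7, just under the high bound, with 100 kb. Other lists moved as well but stayed between the bounds. With 20 kb the retina list lay at 49.6 and the intestine list at 13.2. With 100 kb the pancreas list lay at 33.9, the liver list at 6.14 and the germline list at 24.3. In replicate 1 alone the intestine list lay at 56.8, and in replicate 2 alone the skeletal muscle list at 54.8 and the germline list at 16.1.

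Of the Hox genes, which pattern the body axis, the anterior and trunk list was high and the posterior list was not, though the difference between them was not tested. The 27 anterior and trunk Hox genes (paralogues 1 to 9) had a median of 10.8% against 5.98% in random lists (99.9th percentile), with Hoxb1 at 17.7%, Hoxa5 and Hoxa6 at 15.9% each and Hoxd1 lowest at 2.24%. The 12 posterior Hox genes (paralogues 10 to 13) had a median of 4.06% (20.2nd percentile), with Hoxa10 at 6.73% and Hoxb13 at 0. That percentile depended on the matching, with 84.2 on gene length and 7.99 on GC content, and was 30.95 in replicate 1 alone. Members of a cluster share most of their windows, Hoxa5 and Hoxa6 lying 4.13 kb apart, so they are not independent of each other and the percentile overstates how firmly the list stands apart. With a window of 20 kb the anterior list lay at the 82.0th percentile, with 100 kb at the 97.2nd and with the 50000 strongest peaks at the 94.7th. Housekeeping genes had the 98.9th percentile (median 7.34% of 20 genes). They included the ribosomal protein genes Rplp0 at 22.3%, with much of the gene Pxn in its window, and Rpl13a at 13.3%. Ywhaz had 12.3% and the X-linked Hprt 0. The housekeeping call ended with a 100 kb window (93.9th percentile) and with the number of peaks as the measure (95.9th). Olfactory receptor genes, which are expressed in the nose, had a median of 0%, with 999 of 1134 genes without a replicated peak, and vomeronasal receptor genes likewise with 315 of 328. Both lists lay at the 0th percentile in each replicate, and at the 50th among lists matched on GC content, whose median was then also 0. Over all lists, 9 of the 10 high calls were also made in each replicate alone, hedgehog being the exception, and both low calls were.

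Replicated peaks lay closer to genes than shuffled positions did. Their midpoints lay within 1 kb of an annotated TSS in 22.3% of cases, against 6.44% (range 6.27 to 6.72) in 100 shuffles within chromosomes, a ratio of 3.46. A further 4.66% lay in exons and 51.3% in introns, against 3.44% and 40.6% in the shuffles. Between genes lay 21.7%, against 49.6%. The replicates differed little, with 19.3% ± 0.00931 (SD, n = 2) in promoters, 52.3% ± 0.413 in introns and 23.8% ± 0.336 between genes, so each departure from the shuffles was larger than the spread between replicates. Most midpoints thus lay more than 1 kb from any annotated TSS. Distances to protein-coding genes were taken from 1 outermost start per gene, so alternative promoters did not count as starts. By that measure 10.6% of replicated peaks were within 1 kb, 27.1% at 1 to 10 kb, 45.7% at 10 to 100 kb and 16.6% beyond 100 kb. The shuffles had 42.2% beyond 100 kb. The median distance to the nearest such start was 21.0 kb against 68.9 kb in the shuffles.

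At protein-coding starts H3K4me1 formed flanks around a dip, and the shape depended on the CpG content of the promoter. Over all 21911 starts, 7.20% were covered at the TSS itself and 23.3% at 1100 bp downstream, the highest point, a ratio of 0.308. Upstream the highest coverage was 14.7%, at 600 bp. At the 8393 CpG-rich promoters, the class that holds most housekeeping genes, 4.94% were covered at the TSS, 40.6% at 1200 bp downstream and 25.3% at 700 bp upstream, and the ratio was 0.122 (0.147 in replicate 1 and 0.115 in replicate 2). The 4741 intermediate promoters had 11.8% at the TSS and 29.7% at 900 bp. The 8777 CpG-poor promoters, typical of tissue-specific genes, had no dip, with 6.85% at the TSS and 7.04% at 100 bp (ratio 0.972, and 0.970 and 0.947 in the replicates). No more than 7.04% of these starts were covered at any step, and expression was not examined here. Whether the active ones among them have a dip therefore stays open.

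**Figure D2:**
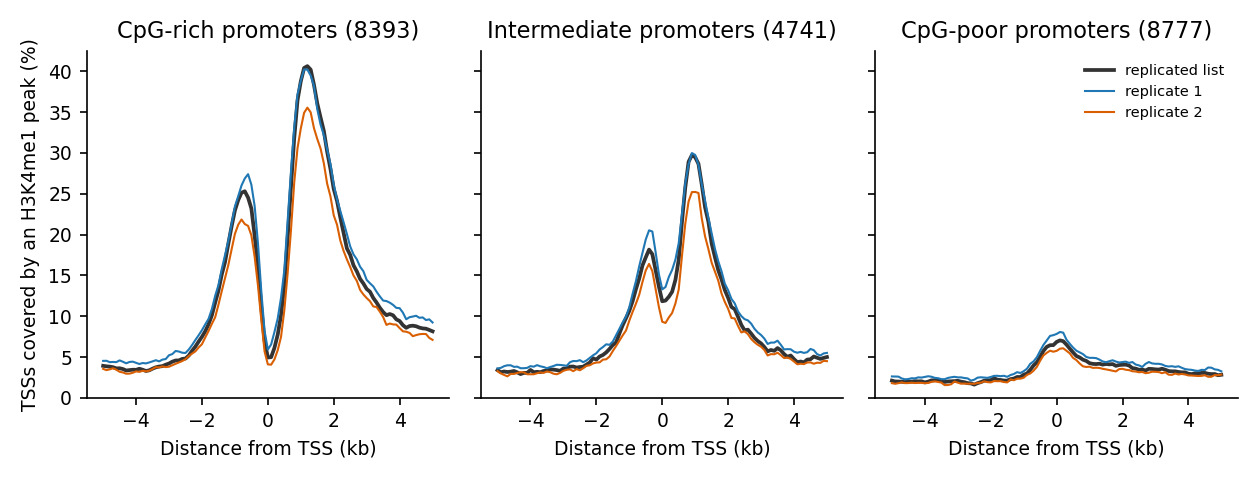
Percent of protein-coding TSSs covered by an H3K4me1 peak (y axis) by distance from the TSS in kb, negative upstream (x axis), for 3 classes of promoter CpG content with the number of genes in each title. The thick line is the replicated list and thin lines the separate replicates; CpG-rich promoters fall to 4.94% at the TSS between flanks of 25.3% and 40.6%, and CpG-poor promoters have no dip, with 6.85% at the TSS and 7.04% at 100 bp downstream.

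The share of regions found in the other replicate rose with significance. Of the regions of replicate 1, 37.8% (95% Wilson interval 37.55 to 38.02, for the counting of regions only, with neighbouring regions taken as independent) had at least 50% of their length in a region of replicate 2, and 50.3% (50.02 to 50.54) of replicate 2 regions were so covered by replicate 1. Shuffled positions gave 1.93% and 2.67%. The Jaccard index over bases was 0.321 against 0.0123 in shuffles. With the regions in 10 equal groups by significance, the share rose from 20.4% in the least significant group to 76.5% in the most significant in replicate 1 and from 32.1% to 86.0% in replicate 2, each set against the whole list of the other. With both lists limited to their 50000 peaks of highest enrichment the shares were lower, 35.2% of replicate 1 and 41.4% of replicate 2, so most of the peaks that stood highest by enrichment in 1 replicate were not so covered by those of the other. The share depended on the overlap asked for: any overlap gave 51.6% and 62.0%, and an overlap of 80% gave 19.8% and 32.0%. Regions with no overlap in the other replicate made up 48.4% of replicate 1 and 38.0% of replicate 2 and were weaker, with median enrichment values of 2.98 and 3.06 against 3.47 and 3.58 in shared regions. The widest of them lay near Epb41 in replicate 1 (1748 bp, chromosome 4, 132075624 to 132077371) and near Tiam2 in replicate 2 (1458 bp, chromosome 17, 3281575 to 3283032). Over 61401 shared regions the enrichment values of the replicates had a Spearman correlation of 0.334 and a Pearson correlation of 0.354 on the log2 scale. These are correlations across regions, which are not independent replicates. Only regions called in both lists entered them, so they do not measure how the signal agreed over all positions.

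**Figure D3:**
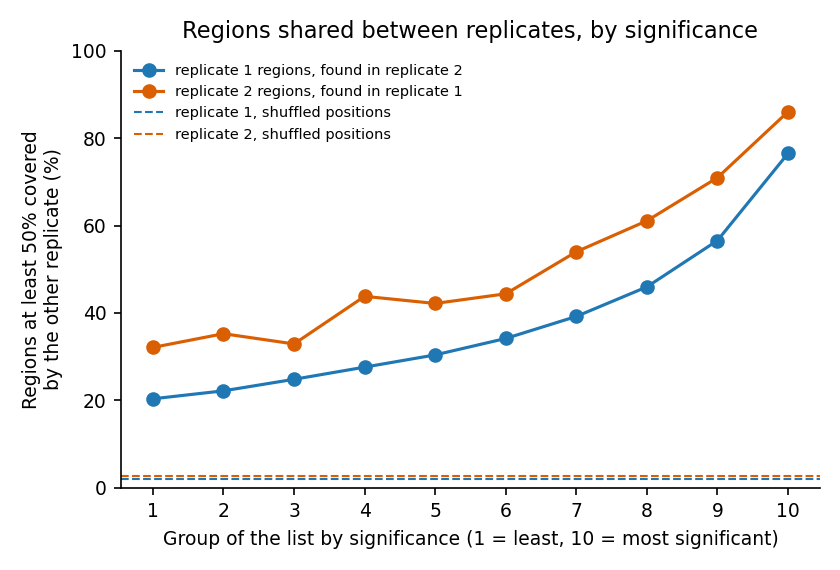
Percent of regions of each replicate with at least 50% of their length covered by the other replicate (y axis), for 10 equal groups ranked by significance (x axis, 1 least significant). Dashed lines give the mean of 100 shuffles, 1.93% and 2.67%; the share rises to 76.5% in replicate 1 and 86.0% in replicate 2 in the most significant group.

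The replicated list was a subset of the pooled list. All of its 92103 peaks had the same coordinates as a pooled peak, and they made up 54.3% of that list. The share kept rose with enrichment, from 23.2% of the weakest 20% of pooled peaks to 96.8% of the strongest 20%. Each of the 73157 pooled peaks that overlapped a peak of replicate 1 and a peak of replicate 2 by at least 50% of either peak's length was listed. A further 18946 listed peaks lacked such an overlap in 1 or both replicates. Of the listed peaks, 89.3% had at least 50% of their own length in replicate 1, 73.9% in replicate 2 and 64.8% in both. Restricting every list to its 50000 strongest peaks lowered the last share to 30.4%, and peaks with −log10 q of at least 2 lowered it to 43.8%.

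Peaks were unevenly spread over chromosomes. On autosomes the replicated list had 27.4 peaks per Mb on chromosome 14 to 61.2 on chromosome 11, with a median of 39.4. The X chromosome had 2.04. In the separate lists it had 4.62 peaks per Mb in replicate 1 and 5.77 in replicate 2, where autosomes had at least 49.4 and 43.2. No peak of any list lay on the Y chromosome. Of the 9 X-linked members of the lists other than the receptor families, 6 had no replicated peak in their windows, and the others were Opn1mw at 0.222%, Flna at 1.51% and Pgk1 at 1.53%. Leaving out X-linked and Y-linked genes, an alternative added after this was seen, gave 8 high lists in place of 10, with the pan-epithelial list at the 97.98th and the matrix list at the 97.9th percentile, just short of the bound of 98.

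**Figure D4:**
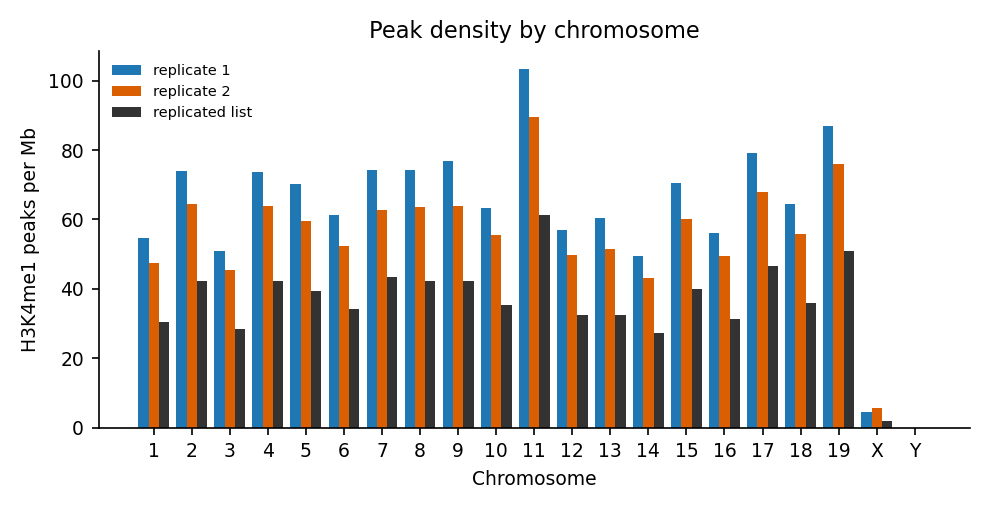
H3K4me1 peaks per Mb of assembled sequence (y axis) on each chromosome (x axis) in replicate 1, replicate 2 and the replicated list. The X chromosome has 4.62, 5.77 and 2.04 peaks per Mb, and the Y chromosome has none.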

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

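All alternatives were chosen before the data were examined except the limit to autosomes. Of 94 values of the main results under the alternatives, 43 moved by no more than the spread between replicates or the 95% interval (for counts, by no more than 1.5 times) and 51 by more. For shares that interval covers the counting of regions only, so small shifts pass it. No direction reversed where the comparison allowed it, in the enrichment correlation and the ratios to background. Promoters stayed above and intergenic sequence below the background. The TSS ratio cannot exceed 1, since its highest point comes from the same profile, so it could not reverse. Read depth is unknown here, which limits any statement on weak peaks, and fewer peaks under a stricter threshold follow from its construction; for the other shifts the cause was not tested.

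With −log10 q of at least 2, replicate 2 kept 90904 peaks, shared regions were 35.4% of replicate 1 and 51.3% of replicate 2, the enrichment correlation was 0.308, 43.8% of replicated peaks lay in both replicates, 66.4% of pooled peaks were kept and the promoter ratio to background was 3.52. With the 50000 strongest peaks of each list (50000 by construction in all 4), the shares were 35.2% and 41.4%, the correlation 0.293, 30.4% lay in both, 92.1% of pooled peaks were kept, the ratios were 3.81 in promoters, 1.252 in introns and 0.403 between genes, and the TSS ratio was 0.257. Any overlap gave shares of 51.6% and 62.0%, a correlation of 0.291 and 80.7% in both replicates. An overlap of 80% gave 19.8%, 32.0% and 21.9%. Equal numbers of peaks gave 40.4% and 47.3%, and mean enrichment a correlation of 0.290.

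Using each replicate alone, the promoter ratio was 3.01 to 3.02, the intron ratio 1.28 to 1.30, the intergenic ratio 0.474 to 0.484, the TSS ratio 0.291 to 0.351 and that of CpG-rich promoters 0.115 to 0.147. The pooled list gave 3.005, 1.29 and 0.484 for the first 3. A 2 kb promoter gave 2.90, 1.15 and 0.417, a circular shift a promoter ratio of 3.51 and the summit 3.49. Of the first 10 domains, 6 to 7 overlapped the first 10 of a single replicate (6 without replicate 2), 5 those of the pooled list, 6 with a 2 kb gap and 4 with a 12 kb gap. The number of high gene lists fell to 5 with GC matching and lay between 7 and 11 in the other settings. GC matching compares each list with genes in the same of 5 bins of window GC content, and replaces the matching on gene density. Of the 10 high lists, 3 were high in all 11 alternatives (Wnt, BMP and TGF-beta, FGF and Notch), and no list went from high to low or back. Of 875 values of the 125 named genes under 7 alternatives, 445 moved by less than the SD of the replicates and 430 by more.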

Other observations

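Of the tests in this part, those of the Hox genes within 5 kb, the retinoic acid list, the CpG-rich X-linked genes, the X ratio without matching and the share of X peaks near escape genes were chosen after the results they follow were seen. Because Ncor2, Rara and Rxra were among the most covered genes, 20 further genes of the retinoic acid pathway, those 3 left out, were examined. Their median coverage was 4.56% against 1.81% in random lists (98.8th percentile, 99.6 and 98.5 in the replicates). The transglutaminase gene Tgm2 had 22.2%, the carrier gene Crabp2 21.9%, the receptor gene Rarg 16.1% and Dhrs3 11.6%. Of the degrading enzyme genes, Cyp26b1 had 12.4%, Cyp26c1 2.32% and Cyp26a1 2.12%. Of the synthesizing Aldh1a enzyme genes, Aldh1a3 had 5.37%, Aldh1a2 2.53% and Aldh1a1 no replicated peak. Among lists matched on GC content the percentile was 79.9.

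Within 5 kb of the Hox starts, the median coverage by replicated peaks was 6.29% in the 15 genes of paralogues 1 to 5, 5.80% in the 12 of paralogues 6 to 9 and 4.18% in the 12 of paralogues 10 to 13, with 4 genes at 0 in each group. The separate lists differed: the medians were 10.7%, 6.50% and 6.999% in replicate 1 and 9.20%, 6.13% and 2.38% in replicate 2. The highest genes were Hoxb2 with 40.1% of its 10 kb covered, Hoxa4 with 35.0%, Hoxa1 with 23.2%, Hoxa2 with 18.3% and Hoxc4 with 15.4%.

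The X chromosome had few H3K4me1 peaks, 917 or 0.540% of the pooled list. Gene density, base composition and repeat content go with part of the deficit but not all of it: X windows of 1 Mb had 0.0799 times the pooled peaks of all autosomal windows, and 0.257 times those of autosomal windows matched on all 3 (bootstrap interval 0.206 to 0.308). A lower X copy number in mixed-sex pools stays open. X peaks with enrichment of at least 4.5 were 0.441 times as dense as matched autosomal peaks of at least 6 (interval 0.112 to 0.876). That ratio rests on few peaks, 0.0556 per Mb over 162 X windows against 0.126 in matched windows. The pair of bounds also assumes that a lower copy number lowers the enrichment value in proportion. If the controls had the same lower copy number, a ratio to them would not fall in that way. The test could then not address copy number. The test of a dose scaled by 0.5 could decide nothing, because its bound of 3 lies near the median of called X peaks (2.90). Its bound of 6 lies in the far tail of autosomal peaks, which fixes a ratio far above 1 (20.5). Whether the remaining X peaks lie at genes escaping X inactivation was examined with a list of 10 such genes. Those genes had a median of 0.759% of their windows in pooled peaks, at the 99.5th percentile of random X-linked lists. The random lists had a median of 0, so a small coverage was enough for a high rank. Of the 917 X peaks, 30 (3.27%) lay within 50 kb of the starts of the 10 genes. Most X peaks lay elsewhere, which argues against that account for the genes listed. The list is short, so escape genes outside it stay open. The share expected by position was not computed, so whether X peaks gather at the listed genes was not settled. How the controls covered the X was not analysed here, and sex or X inactivation as a biological cause was not tested by a comparison of groups.

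The most covered X-linked genes in the pooled list were Bcor at 7.501%, Tmem164 at 6.59% and Efnb1 at 4.74%, and 556 of 948 X-linked protein-coding genes had no pooled peak in their windows. Of the 10 escape genes, the 3 with CpG-rich promoters lay at the 83.4th percentile of random lists drawn from the 172 CpG-rich X-linked genes.

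Many regions of 1 replicate had no counterpart in the other. Calls at uniformly random positions do not account for all of them. Within 10 kb of a protein-coding TSS lay 28.8% of such regions in replicate 1 and 26.9% in replicate 2. These shares were 13.9 and 12.0 percentage points over the highest of 100 shuffles. Background calls that gather near genes were not modelled, so the shuffles cannot exclude them. On a scale from the shuffle mean (0) to the shared regions (1), the regions without a counterpart lay at 0.578 in replicate 1 and 0.496 in replicate 2. The second was just short of the 0.5 set beforehand in both for weaker H3K4me1 regions that miss the other replicate's threshold. That account therefore stays open, as a hypothesis, and a mixture with background calls could give the same values. The replicates were separate pools with separate libraries, and a biological difference between the pools was not tested.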
